A study of Mus musculus with 9 samples.

How the data were processed

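Left ventricular tissue of 9 male C57BL/6 mice was profiled 6 weeks after surgery, 5 after sham surgery and 4 after transaortic constriction (TAC). Per the labels' protocols, tissue was flash frozen, RNA was isolated with Trizol, and the RNA was amplified, labelled with biotin, hybridized and scanned after the array maker's standard protocol. The deposited log2 values were made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects the background of probes, normalizes arrays to a common distribution and summarises the probes of a probe set. In the deposited table every array held the same sorted values, from 2.2511 to 14.799, with a median of 6.5661, so the arrays carry no information on a general rise or fall of RNA. The software that ran RMA is not given in the sources used here. The number of arrays limits the precision. The labels speak of mice in groups of 5 and 4 and list 1 sample per array, with no batch, date or pairing, and replicate numbers are the order of the samples. The labels do not tie each array to its own animal in so many words, so the p-values measure the spread between these samples.

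The table held 45101 probe sets, of which 64 were controls. The platform annotation paired 34945 probe sets with 1 gene symbol and 932 with several, and did not list 9160, which are unnamed here. Of those with 1 symbol, 34741 matched the reference gene table by gene ID and 204 kept the platform's symbol. No symbol needed updating. For each of 18193 genes the probe set with the highest mean over all 9 arrays stood for the gene. There were 9183 genes with 1 probe set and 9010 with several. Controls and probe sets without 1 symbol took no part in the comparison of genes, and no filter on dim genes was applied. All 9 columns belonged to samples of the series. No genome build is given in the sources used here, so no coordinates are printed.

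The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, TAC minus sham, no covariate, two-sided), which gave 7 residual and 3.27 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Adjusted p-values of single probe sets were taken over all probe sets. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Single values of Hipk2 and of the 3' minus 5' control measure were also compared by a two-sided exact permutation test over all 126 splits of 9 arrays into 5 and 4, with a smallest possible p of 0.00794. The 44 gene lists held 791 genes, of which 727 were measured. They covered the HIPK family, ERK signalling, cardiac stress, matrix, cell types, immune genes, metabolism, ion handling and stress responses, and some genes were in several lists. For each list the called members were counted over all genes and adjusted over the list alone. Lists with at least 4 measured members, 43 of them, were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, fry and camera on ranks were alternatives. Principal components and figures were made in R and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

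The genes named by rule were the Hipk genes, 6 known markers of pressure overload, the 12 largest increases and the 12 largest decreases among called genes whose TAC values all lay outside the sham range, and up to 4 called members of each list with the smallest p. Where no member of a list passed, the 2 with the smallest p were named as values. Predicted genes, clone symbols, small RNA genes and receptor families were left out of the largest changes. Members that complete a count of 5 or fewer, and all genes of the closing section's added lists, were chosen after their values were seen. Genes without a probe set of a single name, such as Hipk4, were not analysed here, and some genes are not reported here.

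The fitting steps were tested on simulated data made with the real means and spreads of the 18193 genes. With 200 genes changed, 59.7% of changes of 0.5, 97.0% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 9 of 180 calls were on unchanged genes. With no gene changed there were 0 calls by limma. All 3 lists shifted by 0.5 were called by camera. Genes were simulated as independent, whereas the median correlation estimated within the real lists was 0.107. The simulation therefore does not test the preset correlation of camera.

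The alternatives were the mean of a gene's probe sets, all probe sets, only genes brighter than the median gene, a mean-variance trend with robust fitting, array weights, centring on the median, cyclic loess, a threshold of 1.5-fold, an adjusted p below 0.01, and leaving out each array in turn. Further alternatives were chosen after seeing the data. They were the brightest probe set below 13, the signal of repeat control probe sets as a covariate, and each other Hipk2 probe set. Groups of arrays were searched for outlying arrays with Dixon's ratio, the gap of the extreme array to the next divided by the range, against critical values of 0.829 for 4 and 0.710 for 5 arrays. Intervals of medians are 95% bootstrap intervals over genes from 10000 resamples, and genes are not independent replicates. Counts of calls were compared with those of 100 of the 126 splits, drawn with a fixed seed.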

Results

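Gene expression was measured with Affymetrix mouse expression arrays in left ventricular tissue of male C57BL/6 mice, 6 weeks after transaortic constriction (TAC, n = 4 arrays) or sham surgery (n = 5 arrays). TAC narrows the aorta and makes the left ventricle pump against a raised pressure. The values were RMA values on a log2 scale, 1 per probe set, and each array had the same median of 6.5661. The labels describe groups of mice and list 1 sample per array, and no batch or pairing is given. Differences are TAC minus sham on the log2 scale, with the standard error (SE) of the limma fit and Benjamini-Hochberg adjusted p-values over 18193 genes. The series title names cardiomyocyte HIPK2, a nuclear protein kinase, and ERK signalling, so the Hipk genes and the ERK pathway were examined beside the wider response to TAC.

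By camera with a preset correlation, lists of cardiac stress genes, of collagen and other matrix genes, and of markers of activated fibroblasts and macrophages were higher in the TAC than in the sham ventricles (adjusted p = 0.0855 to 0.122 with an estimated correlation). Lists of genes of fatty acid oxidation, branched-chain amino acid breakdown, the tricarboxylic acid cycle and the respiratory chain, and of cardiac potassium and sodium channels, were lower, although fewer than 1 in 2 respiratory chain genes passed. None of these lists passed with an estimated correlation, where the adjusted p of the lower ones was 0.0855 to 0.283. The matrix gene Comp was 23.1-fold higher, the lysyl oxidase gene Lox 9.64-fold higher and the thioesterase gene Acot1 8.99-fold lower. Hipk2 was nearly level between the groups.

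In the limma fit, 2333 genes were higher and 2233 lower in TAC at an adjusted p below 0.05, together 25.1% of the genes tested, and 6520 genes had an unadjusted p below 0.05. The median size of the called differences was 0.47. At least 2-fold differences were found for 397 higher and 194 lower genes, and at least 4-fold differences for 73 higher and 24 lower genes. The values of the 2 groups did not overlap for 25.2% of all genes, against 1.59% by chance, and 3946 of the called genes were among them. Of the called genes, 51.1% were higher. When each array was centred on its median over the tested genes, 1978 genes were higher and 2908 lower, so that 40.5% were higher, and the median difference over all genes moved to -0.05. The first principal component held 60.9% of the variance and separated all 4 TAC from all 5 sham arrays. Sham replicate 2 stood apart from the other sham arrays, mainly along the second component, which held 15.1%. Pearson correlations across genes were 0.993 to 0.997 between TAC arrays, 0.983 to 0.996 between sham arrays and 0.973 to 0.989 between groups. The 3' minus 5' difference of the actin and GAPDH control probe sets, which rises as RNA degrades, was -0.07 in TAC relative to sham (two-sided exact permutation p = 0.254).

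**Figure D1:**
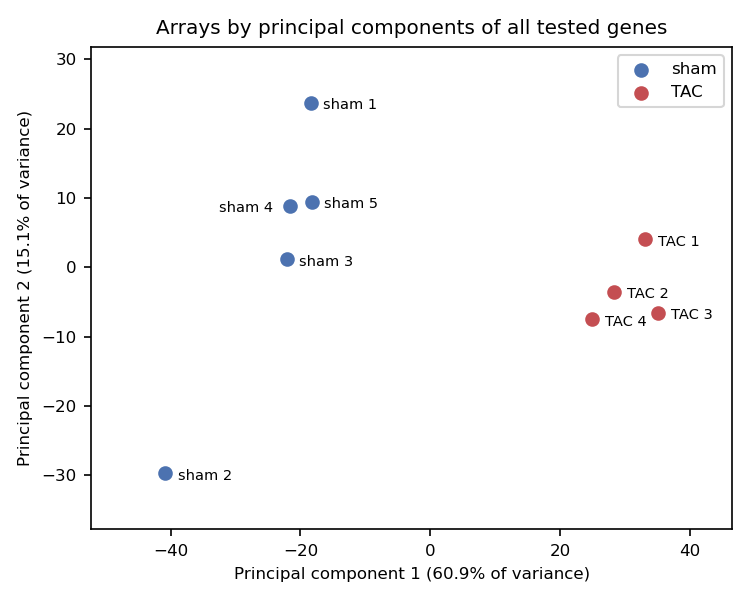
Principal components of the 9 arrays over all tested genes, with the first component (60.9% of variance) on the horizontal and the second (15.1%) on the vertical axis. Each point is 1 array, blue for sham and red for TAC, and sham replicate 2 lies lowest on both components.

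The Hipk genes were not past the threshold. Hipk2, at its brightest probe set, averaged 12.33 ± 0.07 in sham (SD, n = 5) and 12.42 ± 0.04 in TAC (SD, n = 4). Its difference of 0.09 had a 95% confidence interval of -0.05 to 0.22 and an adjusted p of 0.338 in limma, and a two-sided exact permutation p of 0.0635 over all splits of the arrays into 5 and 4. The other 7 probe sets of Hipk2 went in both directions, from -0.53 to 0.18, and none passed the threshold over all probe sets. The mean of the 8 Hipk2 probe sets differed by -0.05. Hipk1, at -0.10 (SE 0.06, adjusted p = 0.285), and Hipk3, at 0.11 (SE 0.09, adjusted p = 0.399), did not pass either, and adjusted over the list alone 0 of the 3 measured family members passed. In limma 0 of the 3 had an unadjusted p below 0.05, and 0 passed with a mean-variance trend and robust fitting. The mean of the 3 Hipk1 probe sets differed by 0.11, opposite to its brightest probe set. The mean of both Hipk3 probe sets did pass, with a difference of 0.26 (adjusted p = 0.00933). Its dimmer probe set was higher by 0.41 with an adjusted p of 0.0496. Hipk4 was not analysed here.

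The known markers of pressure overload also check the sample labels. The natriuretic peptide genes rose, Nppa by 2.14 (SE 0.34, adjusted p = 0.00113) and Nppb by 1.30 (SE 0.27, adjusted p = 0.00539). Myh7 rose by 3.03 (SE 0.27, adjusted p = 3.46e-05) and the skeletal alpha-actin gene Acta1 by 2.19 (SE 0.40, adjusted p = 0.00285), and in all 4 genes each TAC array lay above each sham array. Sham replicate 2 had the lowest value of the sham arrays for each of these genes, and without it the differences were 1.81, 1.03, 2.82 and 1.77. The TAC means of the 4 genes were 13.79 to 14.32, close to or within the range above 14 where few genes were called, so these differences would understate the change if bright values are compressed. The alpha-myosin heavy chain gene Myh6, at -0.05 (adjusted p = 0.561), and the calcium pump gene Atp2a2, at -0.05 (adjusted p = 0.520), did not pass at their brightest probe sets, which averaged above 14. Probe sets of the same genes that averaged below 13 fell, with -0.50 for Myh6 (adjusted p over all probe sets = 0.00828) and -0.71, -0.82 and -1.05 for Atp2a2 (0.00341, 0.000208 and 0.000588), while its 2 others above 13, at -0.09 and -0.05, did not pass (0.430 and 0.675). Of the 14 measured cardiac stress genes 13 rose and 0 fell, and adjusted over the list alone the counts were the same. The list median was 1.36, and its camera test had an adjusted p of 8.97e-11 (adjusted p = 0.0996 with an estimated correlation). Members that rose included the uridine-cytidine kinase gene Uck2 (2.52, SE 0.11), Ccn2 (1.82, SE 0.11), which encodes connective tissue growth factor, and Fhl1 (0.93, SE 0.07).

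**Figure D2:**
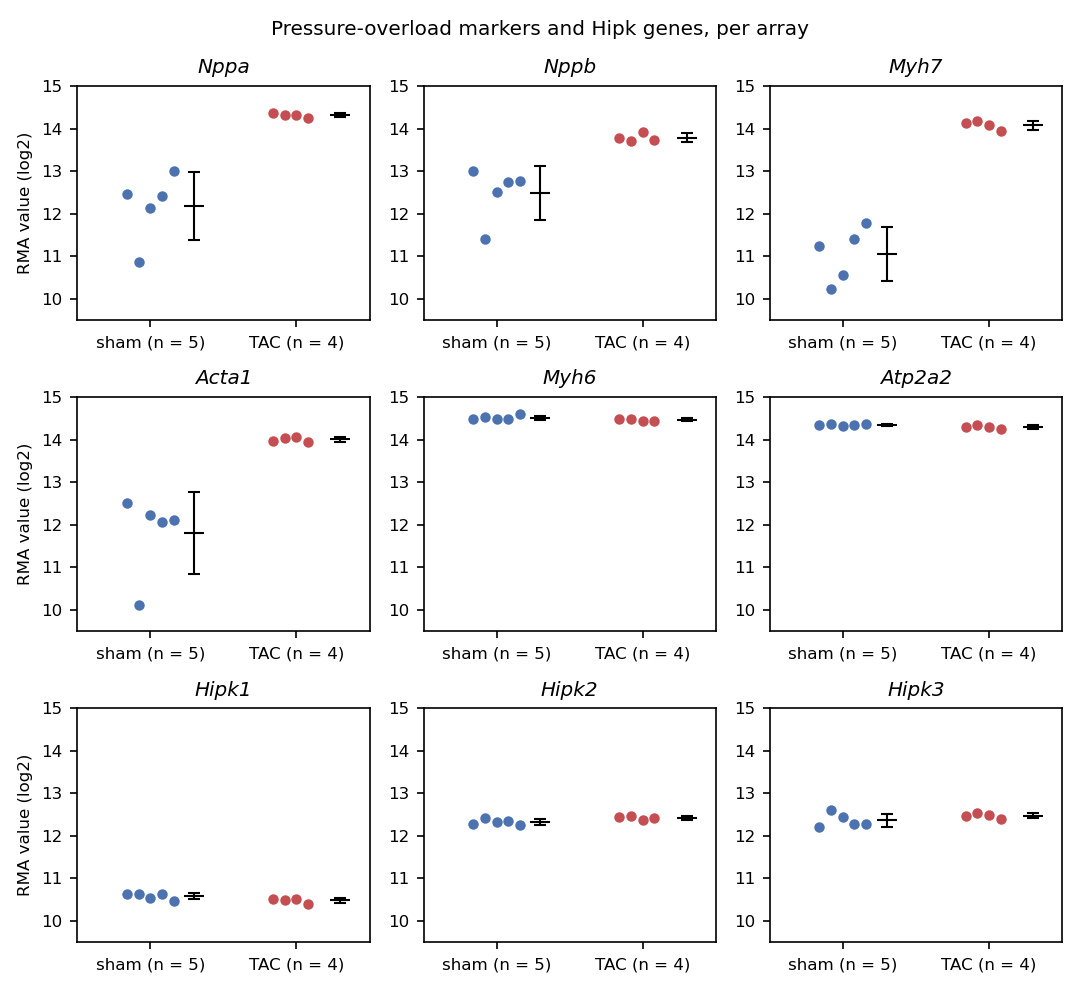
RMA values (log2) of pressure-overload markers and Hipk genes, 1 point per array, with sham in blue (n = 5) and TAC in red (n = 4), and the mean and SD beside the points. Nppa, Nppb, Myh7 and Acta1 do not overlap between the groups, while the brightest probe sets of Myh6, Atp2a2, Hipk1, Hipk2 and Hipk3 differ by at most 0.11.

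The largest increases were in Sprr1a, a small proline-rich protein gene (4.78, SE 0.31, adjusted p = 6.04e-06), the matrix genes Ltbp2, Comp, Cilp, Col12a1 and Fmod (3.97 to 4.72), the deiodinase gene Dio2 (4.61, SE 0.43), the metalloprotease inhibitor gene Timp1 (3.82, SE 0.37), the nicotinamide riboside kinase gene Nmrk2 (3.80, SE 0.34), Thbs4, Tnmd and Pamr1. The largest decreases were in Acot1 (-3.17, SE 0.20, adjusted p = 4.35e-06), the enkephalin precursor gene Penk (-2.79, SE 0.16), Inmt, the cytochrome P450 gene Cyp1a1 (-2.62, SE 0.31), Gpr22, Cenpf, Retnla, Scara5, Ttll1, Nmb, Ces1d and the platelet chemokine gene Ppbp (-2.30, SE 0.41). All 4 TAC values lay outside the sham range in each of these 24 genes, as the rule required. Cenpf, at -2.39, had other probe sets at -0.81 and at 0.38, the last not past the threshold (adjusted p over all probe sets = 0.0794). Col12a1, at 4.15, had others at -0.03, -0.24 and 0.23, and Scara5 had another at -0.07, none of these past the threshold. Ttll1, at -2.34, had others at -0.68 and -0.22, the latter not past the threshold (0.0709).

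**Figure D3:**
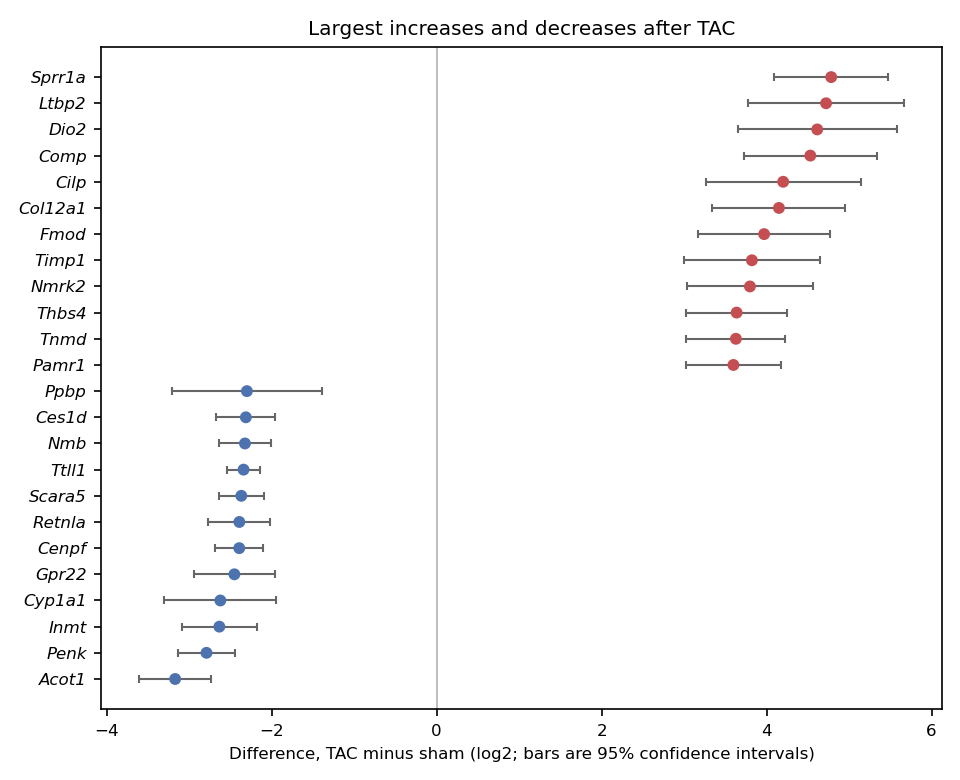
Differences between TAC and sham (log2, points) with 95% confidence intervals (bars) for the 12 largest increases in red and the 12 largest decreases in blue. The differences run from -3.17 for Acot1 to 4.78 for Sprr1a.

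For each gene list fixed before the data were examined, the first counts below are over all genes tested and those in parentheses are adjusted over the list alone. Of 43 lists tested with camera at a preset correlation of 0.01, 13 were higher and 7 lower in TAC. With a correlation estimated for each list, camera called 0 lists, with a smallest adjusted p of 0.0855 and 13 lists at an unadjusted p below 0.05. The rotation test fry, which compares no list with other genes, called 14 lists in each direction. Of the 173 called genes among the 185 named by rule, 168 had all 4 TAC values outside the sham range, the exceptions being Lmod2, Kdr, Ighm, Krt8 and Hyou1. The rule favours such genes, as it took the largest changes among them and list members by the smallest p. Over all 4566 called genes the number was 3946. Genes outside that rule that complete counts of 5 or fewer were chosen after their values were seen, and Nras, Ppp1r1a, Timp4, Myh11, Timd4, Myl4, Nr2f2, Cxcl1, Foxo1, Btg2 and Cdkn1a among them overlapped between the groups. For the 22 counts of 0 in limma given for single directions of the lists, 7 members in all had an unadjusted p below 0.05 in that direction, at most 3 in 1 list, and 2 passed with a mean-variance trend and robust fitting, both immediate-early genes that were lower.

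**Figure D4:**
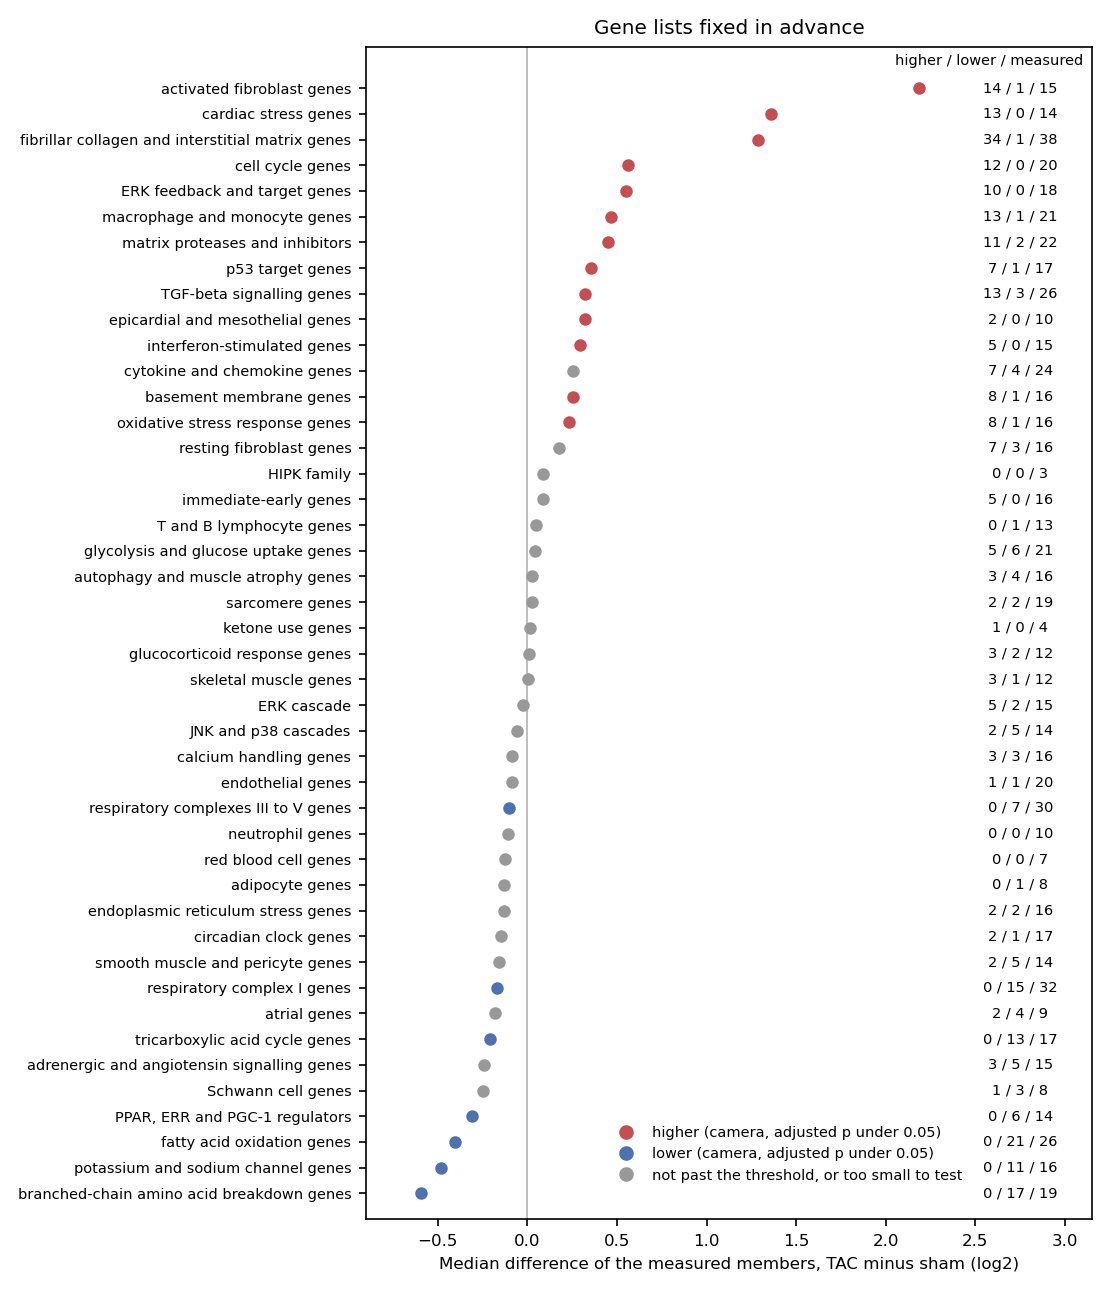
Median difference between TAC and sham (log2) of each gene list, 1 point per list, in red where camera with its preset correlation called the list higher, in blue where it called it lower and in grey otherwise. The numbers at the right give the members higher, lower and measured, and medians run from -0.59 to 2.19.

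Most genes of the extracellular matrix rose. Of 38 fibrillar collagen and interstitial matrix genes 34 rose and 1 fell (35 and 2 adjusted over the list alone), with a median of 1.29 and a camera adjusted p of 2.46e-24 (adjusted p = 0.0855 with an estimated correlation). Lox, which encodes a collagen crosslinking enzyme, rose by 3.27 (SE 0.19), Col8a2 by 3.42 (SE 0.24), Col8a1 by 3.10 (SE 0.23) and the type I collagen gene Col1a2 by 1.28 (SE 0.09). The member that fell was Thbs2 (-0.54), a call that ended without TAC replicate 4 (adjusted p = 0.0638). Among activated fibroblast genes 14 of 15 rose and 1 fell (14 and 1), with a median of 2.19 and an adjusted p of 2.78e-12 (adjusted p = 0.0855 with an estimated correlation). Thbs4 (3.64, SE 0.27), Ccn5 (2.93, SE 0.18), the secreted Wnt inhibitor gene Sfrp1 (1.96, SE 0.10) and Ddah1 (1.45, SE 0.10) rose, and Lrrc17 fell by 0.63. Of 16 resting fibroblast genes 7 rose and 3 fell (7 and 3), with a median of 0.18, or 0.09 without sham replicate 2, and an adjusted p of 0.114. There Pi16 rose by 1.69, Pdgfrl by 1.37 and Medag by 0.94, while Scara5 fell by 2.37, Clec3b by 0.63 and Htra3 by 0.49.

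Of 26 TGF-beta signalling genes 13 rose and 3 fell (15 and 3 adjusted over the list alone), with a median of 0.32 and a camera adjusted p of 0.000215 (adjusted p = 0.154 with an estimated correlation). The ligand genes Tgfb2 (2.04, SE 0.08) and Tgfb3 (1.54, SE 0.15) and the receptor gene Tgfbr2 (0.61, SE 0.07) rose. The co-receptor gene Tgfbr3 fell by 0.80 and Ltbp1 by 0.55, and the third decrease, Acvr2a, lost its call on leaving out any 1 of 8 arrays, with adjusted p up to 0.131 without TAC replicate 2. Among 22 matrix proteases and inhibitors 11 rose and 2 fell (12 and 2), with a median of 0.45 and an adjusted p of 0.000616 (adjusted p = 0.167 with an estimated correlation). Timp1, Adamts8 (2.31, SE 0.13), Mmp23 (1.41, SE 0.13) and the gelatinase gene Mmp2 (1.09, SE 0.10) rose. Adamts5 fell by 0.41, and Timp4 (-1.08) lost its call on leaving out any 1 of 6 arrays, with adjusted p up to 0.0747 without sham replicate 4. Sham replicate 2 had the lowest mean of this list among the sham arrays, 7.50 against 7.76 for the next. Of 16 basement membrane genes 8 rose and 1 fell (8 and 1), with a median of 0.25 and an adjusted p of 0.00275 (adjusted p = 0.325 with an estimated correlation). The type IV collagen genes Col4a3 (1.46), Col4a4 (0.72) and Col4a1 (0.59) rose and the laminin gene Lama5 fell by 0.97.

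Genes of the ERK cascade went in both directions, and 10 of the 18 listed ERK feedback and target genes rose. Of 15 ERK cascade genes 5 rose and 2 fell (5 and 3 adjusted over the list alone), with a median of -0.03, a mean of 0.00, an upward direction in camera and an adjusted p of 0.738. Leaving out 1 array gave medians of -0.08 (without sham replicate 2) to 0.02 (without sham replicate 5). Map2k1, which encodes MEK1, rose by 0.35 (SE 0.07), the phosphatase gene Ptpn11 by 0.31 (SE 0.06), Rps6ka3 by 0.36 and Mknk2 by 0.25. Nras rose by 0.24, a call lost on leaving out any 1 of 6 arrays with adjusted p up to 0.120 without TAC replicate 1. The adaptor genes Gab1 and Grb2 fell by 0.48 (SE 0.11) and 0.39 (SE 0.08). The other probe set of Grb2 differed by -0.04 and did not pass in limma (adjusted p over all probe sets = 0.707). Of 18 ERK feedback and target genes 10 rose and 0 fell (12 and 0), with a median of 0.55 and an adjusted p of 1.48e-05 (adjusted p = 0.167 with an estimated correlation). Emp1 (1.38, SE 0.13), the transcription factor gene Etv5 (1.12, SE 0.12), Ier3 (1.11, SE 0.20) and the ERK pathway inhibitor gene Spred1 (0.46, SE 0.07) rose. Of 14 genes of the JNK and p38 cascades 2 rose and 5 fell (3 and 5), with a median of -0.06 that turned to 0.01 without sham replicate 2, and an adjusted p of 0.374. Map2k6 fell by 1.14, Mapkapk3 by 0.64, the p38-alpha gene Mapk14 by 0.46, Mapk10 by 0.42 and Map3k5 by 0.37. With the mean of its probe sets Mapk14 differed by -0.17 and did not pass (adjusted p = 0.201). Map2k3 rose by 0.32 and Map3k7 by 0.24, the latter not past the threshold without TAC replicate 1 (adjusted p = 0.0569).

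Most genes of fatty acid oxidation and of branched-chain amino acid breakdown fell. Of 26 fatty acid oxidation genes 21 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.40 and a camera adjusted p of 4.86e-12 (adjusted p = 0.0855 with an estimated correlation). With probe sets below 13, 16 of 19 fell and the median was -0.62. Besides Acot1, Eci1 fell by 0.83 (SE 0.07), the thiolase gene Acaa2 by 0.81 (SE 0.08) and the malonyl-CoA decarboxylase gene Mlycd by 0.78 (SE 0.08). Of 19 genes of branched-chain amino acid breakdown 17 fell and 0 rose (17 and 0), with a median of -0.59 and an adjusted p of 4.86e-12 (adjusted p = 0.0855 with an estimated correlation). The branched-chain ketoacid dehydrogenase genes Bckdhb and Bckdha fell by 1.01 (SE 0.07) and 0.78 (SE 0.09), their phosphatase gene Ppm1k by 1.07 (SE 0.12) and Mccc2 by 0.87 (SE 0.08). Among 14 PPAR, ERR and PGC-1 regulators 6 fell and 0 rose (9 and 0), with a median of -0.31 and an adjusted p of 1.48e-05 (adjusted p = 0.0855 with an estimated correlation). Ppara, which encodes a transcription factor that drives fatty acid oxidation, fell by 1.10 (SE 0.12), Rxrg by 0.90 (SE 0.07) and Esrra by 0.49 (SE 0.06).

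Of 17 tricarboxylic acid cycle genes 13 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.21 and a camera adjusted p of 7.97e-06 (adjusted p = 0.106 with an estimated correlation). With probe sets below 13, 7 of 13 fell and the median was -0.21. Suclg2 fell by 0.46, Sdhc by 0.37, Suclg1 by 0.31 and Fh1 by 0.28. Of 32 respiratory complex I genes 15 fell and 0 rose (18 and 0), with a median of -0.17 and an adjusted p of 4.85e-07 (adjusted p = 0.283 with an estimated correlation). With probe sets below 13, 11 of 20 fell and the median was -0.27. Ndufa7 fell by 0.44, Ndufb2 by 0.39 and Ndufs4 by 0.36. Of 30 genes of complexes III to V 7 fell and 0 rose (9 and 0), with a median of -0.10 and an adjusted p of 9.91e-05 (adjusted p = 0.0855 with an estimated correlation). With probe sets below 13, 3 of 9 fell and the median was -0.35. Uqcrc1 fell by 0.37 and Cox7a1 by 0.36. Of 21 glycolysis and glucose uptake genes 5 rose and 6 fell (6 and 6), with a median of 0.04 and an adjusted p of 0.815, and with probe sets below 13 the counts were 6 and 3 of 15 and the median was 0.08. The phosphofructokinase gene Pfkp rose by 1.33, the glucose transporter gene Slc2a1 by 0.79, Pgam1 by 0.42, Pdk1 by 0.38 and Hk1 by 0.27, and Pdk2 and Eno3 fell by 0.39 and 0.34. The call of Hk1 ended on leaving out any 1 of 6 arrays, with adjusted p up to 0.0747 without TAC replicate 3. Of 4 ketone use genes 1 rose and 0 fell (1 and 0), with a median of 0.02 and an adjusted p of 0.652. Bdh1 rose by 0.61, while Acat1 (-0.12), Slc16a1 (0.05) and Oxct1 (-0.02) did not pass. As means of their probe sets Acat1 (-0.28, adjusted p = 0.00419) and Slc16a1 (0.29, adjusted p = 0.00758) did, and Oxct1 changed sign to 0.01 with cyclic loess.

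Of 16 potassium and sodium channel genes 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.48 and a camera adjusted p of 4.85e-07 (adjusted p = 0.0855 with an estimated correlation). Kcnip2, which encodes a subunit of the transient outward channel, fell by 1.18 (SE 0.10), Kcnh2 by 1.18 (SE 0.13), Kcnd3 by 0.66 (SE 0.07) and Kcnq1 by 0.56 (SE 0.06). Of 16 calcium handling genes 3 rose and 3 fell (3 and 4), with a median of -0.08, or -0.05 without sham replicate 2, and an adjusted p of 0.525. The sodium-calcium exchanger gene Slc8a1 rose by 0.52, and Hrc and Cacnb2 fell by 0.78 and 0.47. Dimmer probe sets of Slc8a1, at 0.11 to 0.31, did not pass. The other 3 calls ended on leaving out single arrays, those of Sri without any 1 of 4 arrays (adjusted p up to 0.0876 without TAC replicate 3), of Fkbp1b without any 1 of 4 (0.111 without TAC replicate 2) and of Trdn without any 1 of 6 (0.0972 without TAC replicate 1). Of 19 sarcomere genes 2 rose and 2 fell (0 and 0), with a median of 0.03 and an adjusted p of 0.533, and with probe sets below 13 the counts were 2 and 2 of 9 and the median was 0.01. These were Myom1 (0.23), Lmod2 (0.26), Tnni3 (-0.16) and Nebl (-0.21), and without TAC replicate 3 the 4 adjusted p-values were 0.0540 to 0.122. Of 15 adrenergic and angiotensin signalling genes 3 rose and 5 fell (3 and 7), with a median of -0.24 and an adjusted p of 0.319. The angiotensin-converting enzyme gene Ace rose by 1.45 (SE 0.11) and the receptor kinase gene Grk5 by 0.61 (SE 0.08). Pde4d fell by 1.12, the adenylyl cyclase genes Adcy6 and Adcy5 by 0.81 and 0.30, and the angiotensin receptor gene Agtr1a by 0.75. The remaining calls, Gnai2 (0.23) and Ppp1r1a (-0.38), ended without any 1 of 6 and 4 arrays, with adjusted p up to 0.0784 without TAC replicate 4 and 0.0921 without TAC replicate 3.

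Most macrophage genes rose, and few endothelial genes passed. Of 21 macrophage and monocyte genes 13 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.47 and a camera adjusted p of 4.43e-05 (adjusted p = 0.122 with an estimated correlation). The galectin gene Lgals3 rose by 1.80 (SE 0.29), the fractalkine receptor gene Cx3cr1 by 1.22 (SE 0.11), Adgre1, which encodes F4/80, by 0.97 (SE 0.11) and the complement gene C1qb by 0.68 (SE 0.09). Sham replicate 2 had the lowest sham value for Lgals3 and C1qb, and without it Lgals3 rose by 1.54. Timd4 (-0.35) lost its call on leaving out any 1 of 6 arrays, with adjusted p up to 0.120 without TAC replicate 3. Of 20 endothelial genes 1 rose and 1 fell (1 and 0), with a median of -0.08, ranging from -0.13 without sham replicate 2 to -0.03 without sham replicate 5, and an adjusted p of 0.610. Vwf rose by 0.44, and Kdr (-0.25) lost its call on leaving out any 1 of 6 arrays, with adjusted p up to 0.0859 without TAC replicate 3. Of 14 smooth muscle and pericyte genes 2 rose and 5 fell (3 and 6), with a median of -0.16, or -0.24 with probe sets below 13, and an adjusted p of 0.0994. Abcc9 fell by 0.69, Myh11 by 0.59, the smooth muscle actin gene Acta2 by 0.53, Mylk by 0.48 and Kcnj8 by 0.34, and Tagln rose by 0.53. Pdgfrb rose by 0.25, a call that ended without any 1 of 3 arrays (adjusted p up to 0.0678 without TAC replicate 3).

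Of 10 epicardial and mesothelial genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), the keratin genes Krt18 (3.05, SE 0.19) and Krt8 (0.58, SE 0.13), with a median of 0.32 and a camera adjusted p of 0.0204 (adjusted p = 0.504 with an estimated correlation). This list call ended without TAC replicate 2 (adjusted p = 0.0846) and without TAC replicate 3 (adjusted p = 0.103), and the median was 0.48 without TAC replicate 1 and 0.20 without TAC replicate 3. Of 13 T and B lymphocyte genes 0 rose and 1 fell (0 and 1), with a median of 0.05 that turned to -0.04 without sham replicate 2 and to -0.02 without TAC replicate 1, a mean of -0.02, a downward direction in camera and an adjusted p of 0.960. The 1 was Ighm (-0.56), which did not pass without TAC replicate 3 (adjusted p = 0.0675) and differed by 0.01 as the mean of its probe sets. Of 10 neutrophil genes 0 rose and 0 fell (0 and 0) in limma, with 1 lower at an unadjusted p below 0.05, a median of -0.11 and a camera adjusted p of 0.525. Mmp9 differed by -0.49 (adjusted p = 0.114). Of 7 red blood cell genes 0 rose and 0 fell (0 and 0) in limma, with 3 lower at an unadjusted p below 0.05, a median of -0.12 and an adjusted p of 0.186. Hba-a2 differed by -0.23 (adjusted p = 0.0846), and by a value past the threshold without sham replicate 5 (adjusted p = 0.0282). Of 8 adipocyte genes 0 rose and 1 fell (0 and 1), the lipase gene Lipe (-0.59, and -0.12 with adjusted p = 0.309 as the mean of its probe sets), with a median of -0.13 and an adjusted p of 0.197. Of 8 Schwann cell genes 1 rose and 3 fell (1 and 3), with a median of -0.25, or -0.09 without TAC replicate 4, and an adjusted p of 0.197. Kcna1 fell by 1.77, Gfra3 by 0.84 and Foxd3 by 0.41, and Scn7a rose by 0.32, which did not pass as the mean of its probe sets (0.14, adjusted p = 0.498) or with each array centred (adjusted p = 0.0557). Of 9 atrial genes 2 rose and 4 fell (2 and 4), with a median of -0.18 and an adjusted p of 0.255. Dkk3, a secreted glycoprotein gene, rose by 3.07 (SE 0.19), and Stard10 fell by 1.55, the channel gene Kcnj3 by 1.53 and Tbx5 by 0.97. Myl4 (0.45) lost its call on leaving out any 1 of 2 arrays (adjusted p up to 0.0561 without TAC replicate 1) and Nr2f2 (-0.34) any 1 of 3 (0.0780 without TAC replicate 3). Of 12 skeletal muscle genes 3 rose and 1 fell (3 and 1), with a median of 0.01 and an adjusted p of 0.641. Mybpc2 rose by 1.27, Myoz1 by 0.79 and Tnnt3 by 0.46, and Tnni2 fell by 0.61, or -0.23 as the mean of its probe sets (adjusted p = 0.0576).

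Of 24 cytokine and chemokine genes 7 rose and 4 fell (9 and 4 adjusted over the list alone), with a median of 0.25 and a camera adjusted p of 0.153. The interleukin gene Il6 rose by 2.08 (SE 0.39) and Ccl8 by 1.71 (SE 0.28), and Il15 fell by 1.56 (SE 0.13), the eosinophil chemokine gene Ccl11 by 1.49 (SE 0.14) and Cxcl12 by 0.45. Cxcl1 (-0.63) did not pass without TAC replicate 2 (adjusted p = 0.0511). Of 15 interferon-stimulated genes 5 rose and 0 fell (5 and 0), with a median of 0.29 and an adjusted p of 0.0132 (adjusted p = 0.554 with an estimated correlation). Without sham replicate 2, which had the lowest mean of this list, the median was 0.17. Mx1 rose by 0.78, Ifit2 by 0.64 and Oasl2 by 0.90. Ifit3 (0.71) did not pass without TAC replicate 3 (adjusted p = 0.0564), and Ifit1 (0.61) did not on leaving out any 1 of 4 arrays (adjusted p up to 0.0897 without TAC replicate 3). The list call also ended with fry (adjusted p = 0.0920), with the repeat control signal as a covariate (0.0692) and among genes brighter than the median gene (0.0504).

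Of 20 cell cycle genes 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.56 and a camera adjusted p of 4.70e-05 (adjusted p = 0.359 with an estimated correlation). Tpx2 rose by 0.91, Plk1 by 0.56 and Aurkb by 0.46, all 3 genes of mitosis. Outside this list the mitosis genes Cenpf and Pttg1 fell, by 2.39 and 0.34 at their brightest probe sets. The list did not pass among genes brighter than the median gene (adjusted p = 0.153), and sham replicate 2 had its lowest sham mean, 6.42 against 6.91 for the next array. Of 17 p53 target genes 7 rose and 1 fell (8 and 1), with a median of 0.36 and an adjusted p of 0.00786 (adjusted p = 0.155 with an estimated correlation). Phlda3 rose by 1.29, Zmat3 by 0.71 and Aen by 0.42, and the death receptor gene Fas fell by 0.42. Of 16 oxidative stress response genes 8 rose and 1 fell (8 and 1), with a median of 0.23 and an adjusted p of 0.00311 (adjusted p = 0.153 with an estimated correlation). The NADPH oxidase gene Nox4 rose by 1.39, the glutathione peroxidase genes Gpx3 and Gpx1 by 0.81 and 0.75 and Srxn1 by 0.61, while the mitochondrial superoxide dismutase gene Sod2 fell by 0.28.

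Of 16 immediate-early genes 5 rose and 0 fell (6 and 3 adjusted over the list alone), with a median of 0.09, ranging from -0.06 without TAC replicate 1 to 0.20 without TAC replicate 4, and a camera adjusted p of 0.370. Egr2 rose by 1.95, Egr3 by 1.64 and Nr4a3 by 1.05. The other probe set of Egr3 differed by -0.05 (limma adjusted p over all probe sets = 0.745). Dimmer probe sets of Nr4a3 differed by 0.03 and -0.05 and did not pass either. Atf3 (1.64) did not pass without TAC replicate 3 (adjusted p = 0.0511) or TAC replicate 1 (0.0566), and Btg2 (0.68) did not on leaving out any 1 of 5 arrays (adjusted p up to 0.124 without TAC replicate 3). Of 16 endoplasmic reticulum stress genes 2 rose and 2 fell (2 and 4), with a median of -0.13, or -0.09 without TAC replicate 4, a mean of 0.01 and an adjusted p of 0.374. Atf4 rose by 0.61 beside Atf3, Herpud1 fell by 0.92, and Hyou1 (-0.37) lost its call without any 1 of 8 arrays (adjusted p up to 0.127 without TAC replicate 2). Of 16 autophagy and muscle atrophy genes 3 rose and 4 fell (4 and 4), with a median of 0.03 and an adjusted p of 0.783. Becn1 rose by 0.44, Gabarapl1 by 0.36 and Sqstm1 by 0.33, and Foxo3 fell by 0.51. The other decreases, in Foxo1, Ulk1 and Map1lc3a (-0.21 to -0.24), each ended on leaving out single arrays, with adjusted p up to 0.145 for Foxo1 without TAC replicate 3 and 0.113 for Ulk1 and 0.0883 for Map1lc3a without TAC replicate 1. Of 17 circadian clock genes 2 rose and 1 fell (2 and 1), with a median of -0.15, ranging from -0.29 without TAC replicate 4 to -0.09 without TAC replicate 2, and an adjusted p of 0.642. Bhlhe40 and Bhlhe41 rose by 0.94 and 0.68, and Hlf fell by 1.11. Of 12 glucocorticoid response genes 3 rose and 2 fell (3 and 2), with a median of 0.01, or -0.06 with probe sets below 13, and an adjusted p of 0.744. The metallothionein gene Mt2 rose by 1.10, Fkbp5 by 0.50 and Klf9 fell by 0.52. As the mean of its probe sets Fkbp5 differed by 0.15 (adjusted p = 0.142). Sgk1 (-0.34) did not pass without TAC replicate 3 (adjusted p = 0.0643) or TAC replicate 1 (0.0571), and Cdkn1a (0.50) did not on leaving out any 1 of 6 arrays (adjusted p up to 0.0909 without TAC replicate 3). When each array was centred on its median, the medians of the sarcomere, lymphocyte, skeletal muscle, glycolysis, ketone, autophagy and glucocorticoid lists, none of them called, lay below 0. On leaving out single arrays the median of the skeletal muscle list ranged from -0.05 to 0.05 and that of the glycolysis list from 0.02 to 0.06, and those of the sarcomere (0.01 to 0.04), ketone (-0.01 to 0.04), autophagy (0.01 to 0.04) and glucocorticoid (-0.01 to 0.05) lists also stayed near 0.

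The brightest probe sets differed little between the groups. Of the 46 genes that averaged 14 or more, 6.52% were called, against 32.1% of the 265 genes between 13 and 14. There were 96 genes with a brightest probe set at 13 or more and another between 8 and 12. In 87 of them, or 90.6%, the dimmer probe set differed more between the groups, in the same direction or not. In limma 47 of the dimmer against 17 of the brightest probe sets passed. Of the other 200 probe sets of the 95 called named genes that have several, 110 passed in the same direction and 0 in the opposite one in limma.

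**Figure D5:**
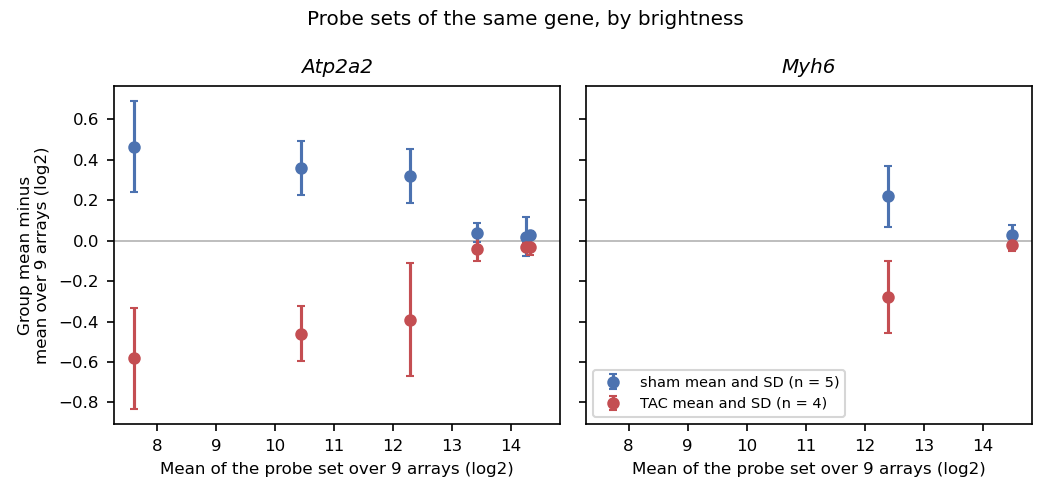
Group means of each Atp2a2 and Myh6 probe set as deviations from its mean over the 9 arrays (log2, vertical), against that mean (log2, horizontal), with SD bars, sham in blue (n = 5) and TAC in red (n = 4). The groups lie apart at dimmer probe sets and close together above 13.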

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

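The tests of sham replicate 2 and of tissue composition were chosen only after the results were seen, while the tests of bright probe sets and of other splits were set beforehand. Dixon's ratio marked an outlying array in 27 of 462 groups of values (5.84%), and chance marks about 1 in 20. Sham replicate 2 accounted for 11 of the 27, among 231 sham groups. It was lowest for Acta1 (0.814), Timp1 (0.724), Slc8a1 (0.712), C1qb (0.811), Lgals3 (0.712), Ifit3 (0.755), Tpx2 (0.834) and Bhlhe41 (0.767), and for the means of the matrix protease (0.854) and cell cycle (0.780) lists, and highest for Mapk14 (0.805). TAC replicate 4 was highest for Cenpf (0.925), Tnni3 (1), Kdr (0.900) and Pdk2 (0.833), and lowest for Spred1 (0.833), Lgals3 (0.878) and the mean of the TGF-beta list (0.864). TAC replicate 3 was highest for Uck2 (0.890) and lowest for Mmp23 (0.873) and Cox7a1 (0.910). TAC replicate 1 was lowest for Lipe (0.884) and TAC replicate 2 for the mean of the glycolysis list (0.856). Sham replicate 5 was lowest for Mlycd (0.735) and Fkbp5 (0.711), sham replicate 3 for the mean of the PPAR, ERR and PGC-1 list (0.826) and sham replicate 1 for the mean of the tricarboxylic acid cycle list (0.737). Among 10092 probe sets without a single gene name, which the comparison of genes did not use, 364 were higher and 806 lower in TAC in limma.

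Sham replicate 2 lay apart from the other sham arrays, with 10.13 for Acta1 against 12.07 for the next lowest sham array. Degraded RNA and a TAC heart under a sham label are argued against. Its 3' minus 5' difference of actin and GAPDH controls was 0.901, the lowest of the arrays against a median of 0.926 for the 8 others. Along the axis from the other sham arrays (0) to TAC (1), over called genes, it lay at -0.22, on the far side of sham. These genes were called with it counted as sham, which favours such a position. The first principal component, over all tested genes, was free of that choice. There it lay at -40.85, with the other sham arrays at -22.15 to -18.29 and the TAC arrays at 24.97 to 35.07. On sham replicate 2 the 45 bacterial control probe sets differed from the other sham arrays by a median of -0.0754 (95% interval -0.12 to -0.05). This cannot decide on raised non-specific background, because RMA had already corrected the background and brought the arrays to a common distribution. Extra template from unspliced RNA or genomic DNA cannot be told apart from other causes, since its 3 repeat control probe sets deviated upwards by 0.38, more than the 0.19 of TAC replicate 4 but less in size than the -0.42 of sham replicate 1, and its 71 odorant and vomeronasal receptor genes only by 0.10, below the 0.14 of sham replicate 3 by less than the spread over genes (-0.04, 95% interval -0.11 to 0.06). A difference between animals or a heart with less stress at baseline may also be involved and was not tested.

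The brightest probe sets differed little between the groups, as for Atp2a2 and Myh6, the genes that prompted the test. Larger noise of dimmer probe sets was examined in 1330 genes whose brightest probe set averaged 9.5 to 11. There the dimmer one differed more in 48.7%. This cannot decide on noise, because the comparison was not matched for it. The median SD within groups was 0.05 for genes from 13 to 14 and 0.12 for those from 9 to 11. Among bright genes the dimmer one differed more in 90.6%, and in 90.5% of the 95 left without the prompting gene that qualified. Both shares count larger differences in either direction. Some pairs went opposite ways, as for Ivns1abp (0.10 at the brightest against -0.71) and Sptbn1 (0.02 against -0.51), which a ceiling alone would not give. In limma 47 of the dimmer against 17 of the brightest probe sets of the bright genes passed. With default settings limma draws the spread of every probe set towards 1 common value, which widens small spreads. The brightest Atp2a2 probe set had SDs of 0.02 (sham) and 0.04 (TAC) but an SE of 0.06. A ceiling on bright probe sets could give both the share and the gap in calls. Noise may add to the share, and the fit may add to the gap in calls. All arrays held the same sorted values, so genes at the top of the scale could only exchange fixed values. The brightest probe set of Tpm1 averaged 14.8, at the highest value of the deposited table, and did not differ between the groups. The shared distribution thus sets a limit at the very top. How far it, scanning or hybridization compresses the other bright probe sets stays open. The true size of the change of genes seen only through a bright probe set stays open too.

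Metabolic genes fell in TAC, which a lower share of cardiomyocyte RNA could also give. This is argued against as the whole cause, since 12 sarcomere and calcium handling genes below 13 had a median of -0.10. For 45 fatty acid oxidation and branched-chain amino acid genes it was -0.49, a difference of 0.39 (95% interval 0.23 to 0.80). Brighter sarcomere and calcium handling genes were left out, and some of their dimmer probe sets fell as far as the metabolic genes. Examples were Tnnt2 (-1.40), Atp2a2 (-0.82), Ryr2 (-0.69) and Myh6 (-0.50), and that of Trdn fell by 0.42. The dimmer probe set of Tpm1 rose by 0.26, and that of Ttn (-0.06) did not pass. With each gene's brightest probe set below 13, the list medians were 0.01 (sarcomere), -0.10 (calcium handling), -0.62 (fatty acid oxidation) and -0.59 (branched-chain amino acid breakdown). The activated fibroblast median exceeded the endothelial one by 2.27 (95% interval 1.43 to 3.27). This cannot decide on a larger share of all other cell types alike, as both medians were known and more transcripts per fibroblast could give it. The medians were -0.08 for endothelial, -0.16 for smooth muscle and pericyte, 0.18 for resting fibroblast and 0.47 for macrophage and monocyte genes. More fibroblasts, or more transcripts per fibroblast, and a change of cardiomyocyte metabolism stay open as hypotheses, and tissue RNA alone does not separate them.

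For the number of called genes, only 1 of 100 splits of the 9 arrays, the real one, reached 4566, and the highest other count was 0 by limma. This makes chance unlikely but does not exclude it, as 100 splits resolve no share below 1 in 100. Every other split mixed TAC and sham arrays in at least 1 group, which widens the spread within that group and lowers the count. For the number of called lists at the preset correlation, chance cannot be excluded over all splits. There 10 of 100, the real one included, gave at least the real 20, and the highest other count was 22. The other splits that reached it held 0, 1 or 3 TAC arrays in the group of 4 and so kept part of the real difference, while the 47 splits with 2 TAC arrays reached at most 10 lists.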

How the results depend on the processing

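The alternatives with probe sets below 13, with the repeat control signal as a covariate and with the other Hipk2 probe sets were chosen only after the results were seen. No paired analysis was possible because the replicate numbers are only the order of the samples. Leaving out 1 array gave 1770 to 2386 higher and 1605 to 2529 lower genes, 12 to 15 higher and 7 to 8 lower lists, and a Hipk2 difference of 0.07 to 0.11. Over all 45037 probe sets 3996 were higher and 3991 lower, as more features were tested. By their construction the stricter thresholds gave fewer calls, 981 higher and 642 lower genes at 1.5-fold and 1356 and 1252 at an adjusted p below 0.01. Camera with an estimated correlation called 0 lists higher and 0 lower (13 at an unadjusted p below 0.05), while fry, which does not compare a list with other genes, called 14 higher and 14 lower. Hipk2 reversed to -0.0538 with the mean of its probe sets and to -0.10, -0.12, -0.53 and -0.0866 with single other probe sets, none of these past the threshold. Hipk1 (0.11) and Ighm (0.0105) reversed with the mean of probe sets, and Oxct1 (0.00995) with cyclic loess; the cause was not tested. Of the values of named genes other than Hipk2 under alternatives, 3002 kept their direction and side of the threshold, 71 lost the call, 12 gained it and 3 reversed. Of those of the 20 called lists, 353 kept both and 26 lost the call. Gains by other lists were not tallied, but 15 higher and 8 lower lists were called without TAC replicate 4, and 8 lower with array weights and with the mean of probe sets. Calls of 20 of 173 called named genes ended under the alternatives in this tally, 11 of them on leaving out 1 array. The tallies of named genes leave out both stricter thresholds and the adjustment over all probe sets, which end further calls. In limma Ptpn11 (1.24-fold) did not reach 1.5-fold and Plk1 (adjusted p = 0.0135) did not reach 0.01. Tnni3 did not pass over all probe sets (adjusted p = 0.0922). Genes near either end of the scale limit what can be seen, as 4.92% of genes below a mean of 5 were called and 6.52% of those at 14 or more. At the bright end the common spread in the default limma fit may add to this.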

Other observations

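The tests of platelet transcripts were set before their result was seen, and the overlap of Ide and Fgfbp3 was chosen only afterwards. The 6 added gene lists were written after values of some of their genes were seen and keep those genes, so their counts and medians are no independent test, and the genes named here were chosen after their values were seen. Among 23 amino acid transporter genes 12 rose and 3 fell in TAC, with a median of 0.34. The glutamate transporter gene Slc1a3 rose by 2.07 (SE 0.11) and the leucine transporter gene Slc7a5 by 1.13 (SE 0.21), while Slc36a2 fell by 1.59 (SE 0.07), Slc38a3 by 0.85 and Slc7a1 by 0.44. Of 12 acyl-CoA thioesterase genes 6 fell, Acot1 among them, and 1 rose, with a median of -0.42. Acot3 fell by 2.01 and Acot2 by 0.69 beside Acot1, and Acot9 rose by 0.53. Of 16 genes of NAD synthesis and use 3 rose and 6 fell, with a median of -0.11. Nmrk2 rose by 3.80, Nnmt by 0.93 and Bst1 by 0.67, while Nampt and Nmnat1, of other steps of NAD synthesis, fell by 0.68 and 0.49.

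Of 20 tendon and cartilage genes 10 rose and 1 fell, with a median of 0.21. The tenomodulin gene Tnmd rose by 3.63, Col22a1 by 3.25, Chodl by 2.66, Prg4 by 1.42 and the tendon transcription factor gene Scx by 0.96, and Cnmd fell by 1.60. Of 18 secreted Wnt modulators 4 rose and 2 fell, with a median of 0.11. Dkk3 (3.07), Frzb (2.71), Sfrp2 (2.19) and Sfrp1 (1.96) rose. Wif1 fell by 0.68, and Sfrp5 (-0.38) did not pass without TAC replicate 3 (adjusted p = 0.0563).

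The platelet genes Ppbp (-2.30), Tubb1 (-2.06) and Pf4 (-0.37) were lower in TAC. Of 14 platelet genes 6 fell, these 3 among them, with a median of -0.39. Less platelet RNA in the TAC samples may account for this, but cannot be told apart from other causes here. The 11 platelet genes other than the prompting 3 had a median of -0.31 (95% interval -0.91 to -0.16), just past the bound of -0.3 set beforehand, and -0.20 without sham replicate 2, a condition added after the result was seen. Alox12, Clec1b and Nrgn fell among the 11, and Ppbp and Tubb1 were highest on sham replicate 2.

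Ide, which encodes the insulin-degrading enzyme, took a higher level, 11.52 to 11.82, on sham replicates 1, 2 and 3 and TAC replicate 2, and a lower one, 11.08 to 11.30, on the other arrays. The 4 highest arrays for Ide shared 4 with the 4 highest for Fgfbp3, its neighbour on chromosome 19 in the reference gene table. Both genes were chosen for this pattern, so the overlap is no test of a variable copy number of the Ide and Fgfbp3 region, which cannot be told apart from other causes here, and no DNA was examined.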
